A study of Homo sapiens with 4 samples.

How the data were processed

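Messenger RNA libraries were made from MDA-MB-231 cells after 24 h with Rib_CA or DMSO, with a Hieff NGS MaxUp Dual-mode kit from RNA purified on RNeasy columns, per the labels' protocols. The deposited table holds raw counts, whole numbers that the authors did not normalise, for 20263 genes in 4 libraries. All 20263 row names are human Ensembl gene IDs, of which 19722 are protein-coding, and no row stands for reads without a gene. The submitters' processing notes name the mouse builds GRCm38 and mm10, which do not match human IDs, and the build that was used is not settled here. The aligner, the counting tool, its use of strand and its treatment of reads that fit several genes are not given in the sources used here. Among values from 1 to 10, 67.7 to 70.7% were even, as arises when both mates of a read pair are counted. The counts are therefore taken as reads rather than independent fragments. Intervals and floors treat each count as independent, so they cover counting error only and understate it where both mates were counted.

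Groups and replicate numbers came from the library titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The 2 libraries of a group were compared by chi-square over genes with at least 20 counts in sum. The statistic was 256.6 times its degrees of freedom in DMSO and 265.3 times in Rib_CA, so the libraries of a pair differed by far more than counting noise. Symbols were found for 20148 IDs in a table of gene names, and 20224 IDs were in GENCODE release 29 (GRCh38), from which gene limits, transcript lengths and GC contents of the longest transcript were taken.

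Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13667. Libraries were scaled by TMM, with factors of 0.997 and 0.872 for DMSO 1 and 2 and 1.008 and 1.140 for Rib_CA 1 and 2. The quasi-likelihood test (glmQLFit, robust, and glmQLFTest) compared Rib_CA with DMSO with 2 residual degrees of freedom, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 0.314. Standard errors were obtained as the absolute log2 fold change divided by the root of the test's F. CPM values are counts per 1000000 counts of the library, scaled by TMM and given as mean ± SD over 2 libraries, and fold changes are those of the fit.

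27 gene lists were written down, with the tests, the alternatives and the rule for named genes, before the data were examined. 25 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. camera asks whether a list's genes differ more than other genes do. The correlation was also estimated per list, and fry tested whether a list's genes move, on balance, in one direction. With an estimated correlation none of the 15 list calls held. For some lists the estimate lay far above the preset 0.01, as for mitochondrially encoded genes (0.985) and NF-kB genes (0.606). Calls were also lost where the estimate lay below the preset 0.01, as for p53 targets (0.006) and ATF4 genes (-0.023). That setting tests with the fit's 2 residual degrees of freedom, so its p reflects more than the correlation. The named genes are the 10 largest increases and the 10 largest decreases among genes that passed, had a mean of at least 10 CPM in the higher group and had both Rib_CA libraries beyond both DMSO libraries. To these were added up to 4 members of each list with the smallest p, and CDKN1A, MDM2, BAX, BBC3, PMAIP1, CDK4, CDK6, CCND1 and RB1 whatever their values. This gave 119 genes, of which 60 passed, and 1 further result of the rule is not reported here.

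The alternatives tried were DESeq2's size factors, total counts alone, no filter on low counts, a filter of 5 CPM in at least 2 libraries, the replicate number as a block, each library left out in turn, thinning to 34774542 counts per library, DESeq2 1.42.0 and limma-voom. With a library left out, the lone library of its group is assumed to vary like those of the other group. Chosen after seeing the data were a run without mitochondrially encoded genes, a correction of each library for GC content, a correction for GC content and transcript length, and a crossed pairing of the replicates. The corrections took each gene's log2 CPM less its mean over all libraries. A smooth of these deviations in each library over GC content, or over GC content and length (mgcv 1.9.3, 6 basis functions), was an offset in the same test. The deviations include the treatment difference, so a real change that runs along GC content or length is removed too. Exonic overlaps of named genes with other genes of the table were taken from GENCODE release 29. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

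The fit was tested on simulated data: 5 simulations of Rib_CA against DMSO over 13667 genes, each with 200 changed genes. It recovered 14.9% of the genes changed 2-fold, 75.1% of those changed 4-fold, 94.3% of those changed 8-fold and 98.0% of those changed 16-fold, and 3.62% of its calls were false. A list changed 2-fold was called in 5 of 5 simulations, and 0 of 100 unchanged lists were called. Changes of 2-fold were therefore mostly below what 2 libraries per group could detect. The simulated genes varied independently of one another, and the simulated libraries had no trend with GC content. The shares of false calls and of unchanged lists called may therefore not hold for correlated lists or for libraries that differ along GC content.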

Results

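MDA-MB-231 is a human triple-negative breast cancer cell line. The cells were treated for 24 h with Rib_CA, a compound that the series title calls a ribociclib derivative, or with DMSO, a common solvent for such compounds. Ribociclib inhibits the cyclin-dependent kinases CDK4 and CDK6. RNA was sequenced from 2 libraries per group, 4 in all. The table of gene counts held 34774542 and 37754168 counts for the DMSO libraries and 38865103 and 37772266 for the Rib_CA libraries. Counts above 0 were found for 14939 and 14940 genes in DMSO and for 15036 and 15054 genes in Rib_CA. The floor used here is 3 counts in a library, which would hold for independent counts. A gene at 3 counts lay at 0.0772 to 0.0863 CPM (counts per 1000000 counts of the library) before TMM scaling. Transcripts of the mitochondrial genome took 8.68% of the counts in DMSO 1 (95% Wilson interval 8.67 to 8.69) and 21.7% in DMSO 2 (21.68 to 21.71). Their share was 5.79% in Rib_CA 1 (5.78 to 5.79) and 3.13% in Rib_CA 2 (3.13 to 3.14). These intervals treat counts as independent and are too narrow if both mates of a pair were counted. The group means were 15.2% ± 9.20 in DMSO and 4.46% ± 1.87 in Rib_CA (SD, n = 2). With 2 libraries per group an exact permutation test cannot give a two-sided p below 0.333, and the difference in share was not tested.

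The series title names p53-dependent apoptosis, and the comparison of Rib_CA with DMSO asks which genes the compound changed. In Rib_CA-treated cells, 11 of 24 stress-response genes under ATF4 and 10 of 23 NF-kB and cytokine genes rose, while 22 of 42 mitosis genes, 10 of 21 DNA double-strand break repair genes and 3 of 14 heat shock genes fell. Among called genes with a mean of at least 10 CPM in the higher group, the largest increases were in the chemokine genes CXCL2 (38.4-fold) and CXCL8 (26.7-fold), the cytokine gene IL1B (25.8-fold) and the prostaglandin synthase gene PTGS2 (19.8-fold). At the same limit, the largest decreases were in CENPE (12.4-fold lower) and CENPF (11.7-fold lower), both of the kinetochore, in FAM111B (10.8-fold lower), and in the proliferation marker MKI67 (10.3-fold lower). Outside the fixed lists, C15orf48 rose 10.4-fold, the kinesin gene KIF20B was 9.94-fold lower, the Golgi gene GOLGA4 8.03-fold lower and the tumour suppressor gene APC 7.75-fold lower. Of 13667 genes tested with edgeR's quasi-likelihood test, 275 were higher and 699 lower at an adjusted p under 0.05, which is 7.13% of the genes, and 28.2% of the calls were higher. All 974 called genes differed at least 2-fold and had both Rib_CA libraries beyond both DMSO libraries. Over all genes tested, the groups lay apart in this way for 58.8%, where chance gives 33.3%. With libraries scaled by their total counts alone, 260 genes were higher and 328 lower, so that 44.2% of the calls were higher. That scaling moved the median log2 fold change of all genes by 0.20. The counts moved with single libraries: they were 36 higher and 137 lower without DMSO 1, 53 and 356 without DMSO 2, 1234 and 1634 without Rib_CA 1, and 1145 and 1616 without Rib_CA 2. Of the 60 named genes that passed, 26 passed in all 4 of these fits, and FAM111B lost its call on leaving out either DMSO library. With 1 library left out, the fold change ranged from 11.8 to 64.5 for CXCL2, from 14.7 to 38.6 for CXCL8, from 15.6 to 35.6 for IL1B and from 10.98 to 29.28 for PTGS2, and among the genes that fell from 6.65 to 29.1 for FAM111B and from 5.45 to 13.9 for APC. After each library was corrected for transcript GC content, or for GC content and transcript length, no gene passed in edgeR, with 3650 and 3406 genes at an unadjusted p under 0.05 against 3879 before. The second correction moved 27 of the 60 by over 1.5 times, 26 of them to smaller fold changes: CENPE to 6.42-fold lower, CENPF to 5.98-fold, FAM111B to 6.70-fold, KIF20B to 5.70-fold, GOLGA4 to 4.34-fold and APC to 3.80-fold, while PTGS2 went to 32.5-fold higher. DESeq2 without correction called 991 genes higher and 1464 lower, and limma-voom called 224 and 658.

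**Figure D1:**
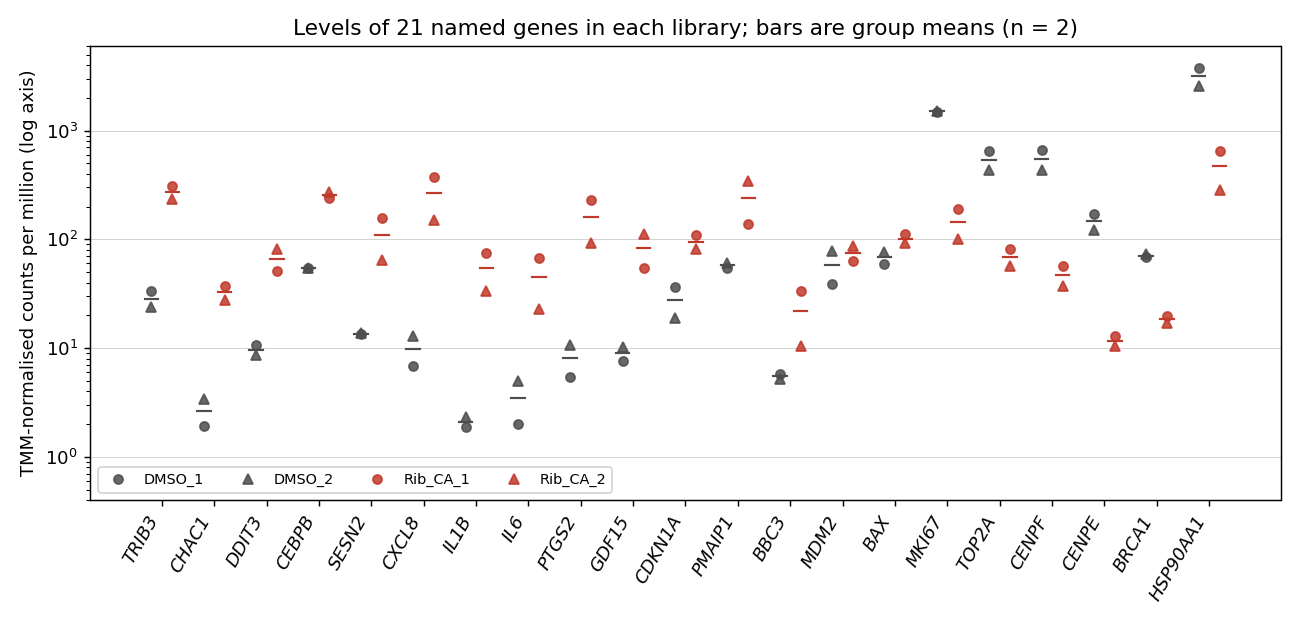
TMM-normalised CPM on a log axis for 21 named genes in each of the 4 libraries (grey, DMSO; red, Rib_CA; circles, replicate 1; triangles, replicate 2), with bars at the group means. MKI67 lay at 1478 and 1518 CPM in DMSO and at 191 and 100.1 CPM in Rib_CA, while MDM2 overlapped between the groups, at 38.6 and 78.4 CPM in DMSO and 62.8 and 86.0 CPM in Rib_CA.

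Genes of the integrated stress response, which the transcription factor ATF4 drives when protein synthesis or amino acid supply is disturbed, were higher in Rib_CA. Of 24 members tested, 11 rose and none fell, and 18 rose when p was adjusted over the list alone. The pseudokinase gene TRIB3 rose 9.57-fold, from 28.5 ± 6.53 to 273 ± 54.7 CPM (SD, n = 2; log2 fold change 3.26 ± 0.32 SE; adjusted p = 0.0285). CHAC1, whose product degrades glutathione, rose 12.2-fold (adjusted p = 0.0285; 7.75-fold after the GC and length correction). CEBPB rose 4.71-fold (log2 fold change 2.237, and 1.585 after correction) and DDIT3, which encodes the stress factor CHOP, rose 6.89-fold. DDIT3 shares 27.2% of its exonic bases with MARS1 on the opposite strand, so that reads on the shared bases were separable only if the counting used strand. The list's median log2 fold change was 1.26, and 1.503 after correction. Its adjusted camera p was 6.7e-18 with a preset correlation, and the adjusted p was 0.252 with an estimated correlation. Endoplasmic reticulum chaperone and unfolded protein response genes did not pass as a list (20 tested; adjusted p = 0.432). The list's median was -0.12 while its mean was 0.18 and the test pointed upward. The median was 0.17 after correction and 0.08 with total-count scaling. Within it, the stress sensor gene ERN1 rose 4.88-fold and the chaperone gene HSP90B1 was 3.05-fold lower, and adjusted over the list alone 2 were higher and 1 lower. Heat shock genes, chaperones under HSF1, were lower: 3 of 14 tested fell and none rose, with 4 lower adjusted over the list alone. HSP90AA1 fell from 3183 ± 842 to 469 ± 258 CPM (6.79-fold, and 4.89-fold to 11.4-fold with 1 library left out; adjusted p = 0.0301), HSPH1 was 4.89-fold lower (3.02-fold after correction) and DNAJA1 3.17-fold lower. The list's median was -0.81, and -1.004 after correction, with an adjusted camera p of 7.0e-05 and an adjusted p of 0.403 with an estimated correlation. CEBPB lost its call without DMSO 1, and HSP90B1 and DNAJA1 on leaving out either DMSO library.

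Genes that NF-kB controls, most of them cytokines and chemokines, held the largest increases among called genes with a mean of at least 10 CPM in the higher group. Of 23 members tested, all 23 had a positive fold change, 10 rose, and 17 rose adjusted over the list alone. CXCL8 rose from 9.90 ± 4.34 to 265 ± 160 CPM (SD, n = 2; adjusted p = 0.0285), and IL6 from 3.49 ± 2.11 to 44.8 ± 31.0 CPM (12.9-fold; adjusted p = 0.0319). CXCL1 rose 19.4-fold, CXCL3 16.6-fold, and RELB, an NF-kB subunit, 5.54-fold (3.64-fold after correction). The Rib_CA libraries differed from each other here: CXCL8 lay at 377.9 CPM in Rib_CA 1 and at 151 CPM in Rib_CA 2, and CXCL2 at 166 and 31.5 CPM. The list's median was 2.85, and 2.69 after correction, with an adjusted camera p of 7.4e-17 and an adjusted p of 0.403 with an estimated correlation. The estimated correlation was 0.606, so the members moved largely together and the camera p at the preset 0.01 overstates the evidence. CCL20, singled out after its values were seen, had no count in DMSO. CCL20 was not called (adjusted p = 0.0562), and its Rib_CA mean was 0.827 CPM. Set over a TMM-scaled floor of 0.0911 CPM in DMSO, that mean was 9.08-fold higher, and this value left the list's median at 2.85. The ratio takes the Rib_CA mean as exact, and the floor would hold only for independent counts. It is therefore not a lower limit of the fold change. Type I interferon response genes were higher as a list (3 of 28 rose and none fell, with 3 adjusted over the list alone). ISG15 rose 3.69-fold (2.34-fold after correction), OASL 3.32-fold and ISG20 3.23-fold. The median was 0.59, and 0.22 after correction. The adjusted camera p was 0.0240, and the adjusted p was 0.502 with an estimated correlation. The list's call was lost without DMSO 1 (median 0.201; adjusted p = 0.128) and without Rib_CA 2 (median 0.127; adjusted p = 0.493). MAPK output genes did not pass as a list (adjusted p = 0.0801; median 0.48, and 0.29 after correction). Within it, DUSP5, a phosphatase of ERK, rose 3.04-fold and IER3 4.41-fold (2.73-fold after correction), 2 of 20 tested and 2 adjusted over the list alone. That list passed without DMSO 2 (adjusted p = 0.00377), without Rib_CA 2 (adjusted p = 0.00669) and with total-count scaling (adjusted p = 0.0337). CXCL1, CXCL2, CXCL3, ISG15, OASL, ISG20 and DUSP5 lost their calls on leaving out either DMSO library, CXCL3 also without Rib_CA 1, and RELB and IER3 without DMSO 1. With 1 library left out, the fold change ranged from 6.30 to 22.4 for IL6, from 7.21 to 31.3 for CXCL1, from 5.76 to 32.3 for CXCL3 and from 2.68 to 6.03 for IER3.

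Targets of p53 were higher as a list, with members on both sides. Of 35 tested, 5 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell. GDF15, a stress cytokine gene, rose from 8.92 ± 1.85 to 83.4 ± 40.1 CPM (9.35-fold; 5.78-fold after correction), and SESN2, which restrains mTORC1, rose 8.11-fold. PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 57.5 ± 4.34 to 240 ± 143 CPM (4.18-fold; adjusted p = 0.0443). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 27.8 ± 12.3 to 95.2 ± 18.8 CPM (3.43-fold; adjusted p = 0.0443), a call lost without DMSO 2. TNFRSF10B, a receptor for the death ligand TRAIL, rose 2.91-fold, and CCNG1 was 3.10-fold lower. MDM2, a classical p53 target, had a log2 fold change of 0.35 ± 0.39 (adjusted p = 0.603), and of 1.27 ± 0.43 after correction (adjusted p = 0.153). BAX had one of 0.57 ± 0.27 (adjusted p = 0.217), and of -0.09 ± 0.21 after correction. BBC3, which encodes PUMA, had a 3.96-fold higher mean that did not pass (adjusted p = 0.0770; 2.41-fold after correction). The list's median was 0.61, and 0.55 after correction, with an adjusted camera p of 0.00209 and an adjusted p of 0.403 with an estimated correlation. Genes of the mitochondrial apoptosis pathway were also higher as a list, but PMAIP1 alone of 18 members passed, and 4 adjusted over the list alone. The median was 0.49, and 0.52 after correction, with an adjusted camera p of 0.0136 and an adjusted p of 0.403 with an estimated correlation. BAK1 had a log2 fold change of 1.22 ± 0.29 (adjusted p = 0.0532). Anti-apoptotic genes did not pass as a list (10 tested; adjusted p = 0.168; median 0.18), and passed after the GC correction (adjusted p = 0.0119) and the GC and length correction (median 0.54; adjusted p = 0.00259). BCL2L2, which encodes the survival protein BCL-w, rose 18.3-fold, from 3.32 ± 1.30 to 60.8 ± 9.27 CPM. It shares 19.4% of its exonic bases with the read-through gene BCL2L2-PABPN1 on the same strand. BIRC6, an inhibitor of apoptosis, was 4.24-fold lower (2.13-fold after correction). Adjusted over the list alone, 2 were higher and 1 lower. MCL1 had a log2 fold change of 1.04 ± 0.29 (adjusted p = 0.0785). The death receptor pathway did not pass as a list (13 tested, TNFRSF10B the 1 that rose, also 1 adjusted over the list alone; adjusted p = 0.0739; median 0.44, and 0.08 after correction). It passed with the stricter filter (adjusted p = 0.0418) and without Rib_CA 1 (adjusted p = 0.0444). PMAIP1, TNFRSF10B and CCNG1 lost their calls on leaving out either DMSO library, and BIRC6 without DMSO 1. With 1 library left out, the fold change ranged from 6.16 to 12.1 for GDF15, from 4.61 to 11.5 for SESN2, from 2.42 to 5.75 for PMAIP1 and from 1.856 to 5.996 for BBC3, and the log2 fold change of MDM2 from -0.081 to 0.947.

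Genes of mitosis were lower as a list. Of 42 members tested, 22 fell and none rose, and 25 fell adjusted over the list alone. MKI67 fell from 1498 ± 28.1 to 145 ± 63.9 CPM (SD, n = 2; log2 fold change -3.37 ± 0.40 SE; adjusted p = 0.0285). TOP2A, the topoisomerase that disentangles chromosomes, was 7.88-fold lower, ASPM, of the spindle poles, 9.55-fold lower, and ANLN, of the cleavage furrow, 7.82-fold lower (4.68-fold, 4.49-fold and 5.06-fold lower after correction). Members that did not pass include CDC20, CCNB1, AURKB, PTTG1, MAD2L1 and CENPA, singled out after their values were seen, with log2 fold changes of -0.014, -0.245, -0.186, 0.074, 0.069 and 0.639, and of -0.623, -0.098, -0.799, -0.334, 0.638 and 0.341 after correction. The list's median was -1.43, and -1.16 after correction, with an adjusted camera p of 2.7e-22 and an adjusted p of 0.403 with an estimated correlation. E2F and DNA replication genes, which CDK4/6 activity releases from RB, were lower as well: 7 of 43 fell and none rose, with 9 lower adjusted over the list alone. Fold changes were negative for 34 of the 43 and positive for 9. Members that did not pass include E2F1, MCM2, CDT1, MCM7 and TK1, singled out after their values were seen. Their log2 fold changes were 0.029, 0.137, 0.099, 0.374 and 0.537, and -0.528, -0.249, -0.404, -0.009 and -0.161 after correction. POLA1, a subunit of DNA polymerase alpha, was 5.03-fold lower, MCM10 4.25-fold lower, and CCNE2, which encodes cyclin E2, 3.74-fold lower (2.49-fold after correction), with 37.0% of its exonic bases shared with INTS8 on the opposite strand. The median was -0.56, and -0.62 after correction, with an adjusted camera p of 7.0e-05 and an adjusted p of 0.460 with an estimated correlation. Genes of DNA double-strand break repair were lower: 10 of 21 fell and none rose, with 15 lower adjusted over the list alone. BRCA1 fell from 70.7 ± 2.64 to 18.4 ± 2.06 CPM (3.86-fold), BRCA2 was 4.65-fold lower and BLM 4.52-fold lower. After correction they were 2.41-fold, 2.16-fold and 2.95-fold lower. The median was -1.22, and -0.74 after correction, with an adjusted camera p of 1.3e-09 and an adjusted p of 0.403 with an estimated correlation. The module of D cyclins, CDK4/6 and RB proteins did not pass as a list (16 tested; adjusted p = 0.727; median 0.06, and 0.00 after correction). In it CDKN1A rose and RBL1, an RB relative, was 2.69-fold lower (1.67-fold after correction), with 2 higher and 3 lower adjusted over the list alone. CDK4 had a log2 fold change of 0.98 ± 0.24 (adjusted p = 0.0605), with 43.2% of its exonic bases shared with TSPAN31 on the opposite strand. CDK6 had one of -1.09 ± 0.30 (adjusted p = 0.0765; -0.04 after correction), RB1 one of -0.98 ± 0.25 (adjusted p = 0.0653; -0.34 after correction) and CCND1 one of 0.12 ± 0.29 (adjusted p = 0.835; -0.108 to 0.271 with 1 library left out). Replication-dependent histone genes did not pass (8 tested, none called and none adjusted over the list alone; median 0.96, and 0.63 after correction; adjusted p = 0.0801). That list passed without Rib_CA 2 (median 1.48; adjusted p = 0.00101). POLA1, CCNE2, BRCA2 and BLM lost their calls without DMSO 1, and RBL1 on leaving out either DMSO library.

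**Figure D2:**
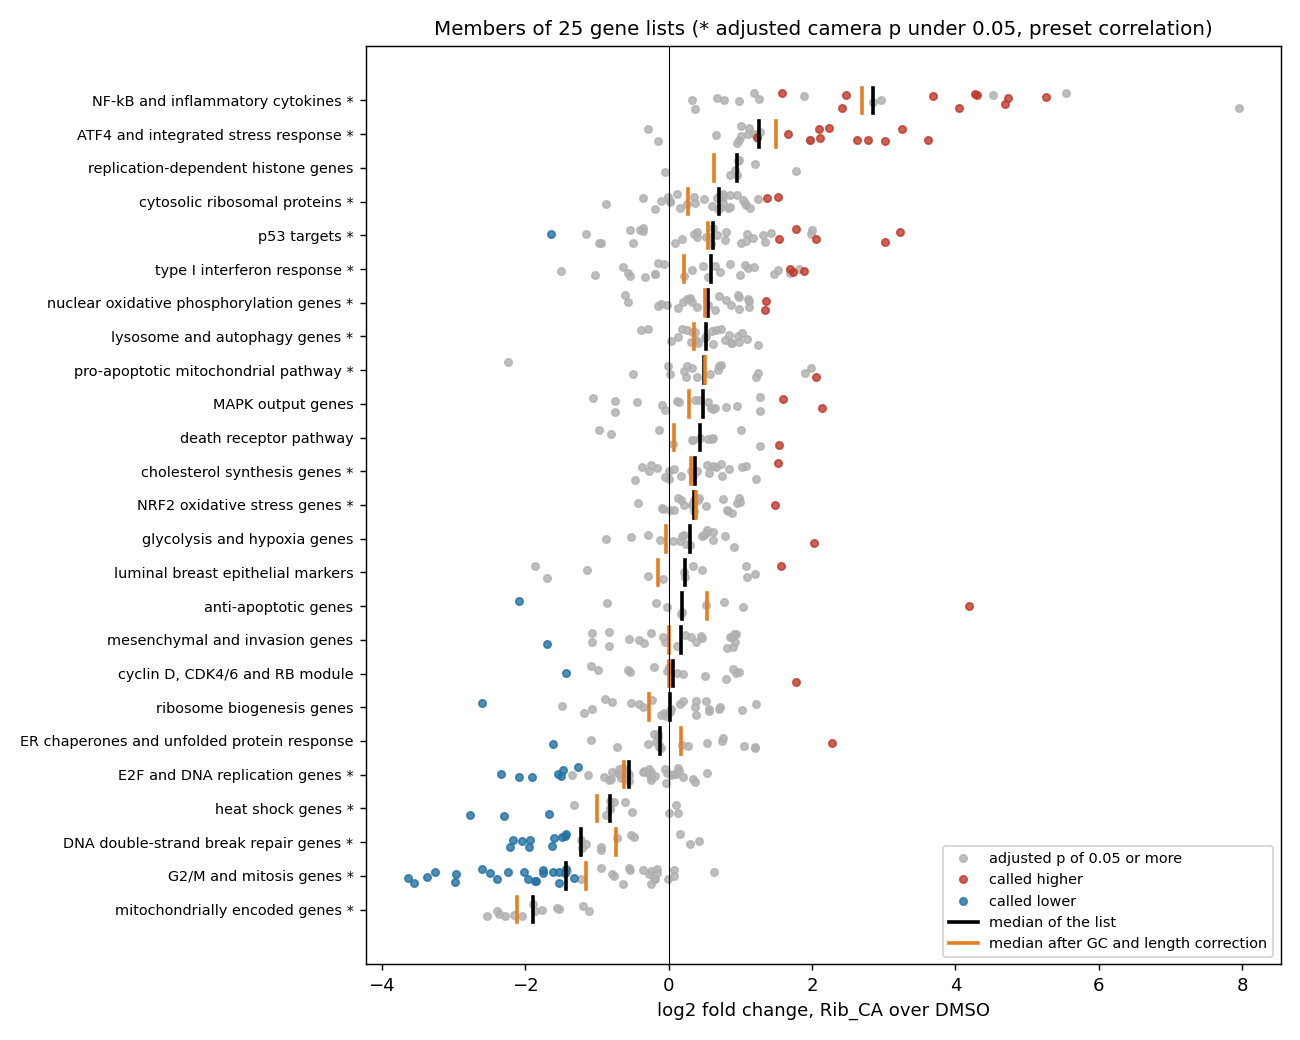
Each point is the log2 fold change (Rib_CA over DMSO) of a tested member of one of 25 gene lists, coloured by its call, with a black bar at the list's median and an orange bar at the median after the GC and length correction. The lists of NF-kB and ATF4 genes have medians of 2.85 and 1.26, and the list of mitosis genes has one of -1.43.

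Messenger RNAs of the mitochondrial genome were lower as a list, with none of 13 passing singly and 9 lower adjusted over the list alone. All 13 fold changes were negative, the median was -1.90, and -2.11 after correction, with an adjusted camera p of 7.6e-06 and an adjusted p of 0.485 with an estimated correlation. MT-ND4 lay at 14360 and 43960 CPM in the DMSO libraries and at 6827 and 3220 CPM in the Rib_CA libraries (adjusted p = 0.0770; 2.86-fold to 9.47-fold lower with 1 library left out). Nuclear genes of the respiratory chain were higher: 2 of 25 rose, COX5B 2.55-fold and NDUFA1 2.55-fold, and 9 rose adjusted over the list alone. NDUFA1 shares 44.5% of its exonic bases with RNF113A on the opposite strand. The median was 0.55, and 0.50 after correction, with an adjusted camera p of 0.000687 and an adjusted p of 0.460 with an estimated correlation. Cytosolic ribosomal protein genes were higher: 2 of 32 rose, RPLP1 2.59-fold and RPS19 2.87-fold, and 7 rose adjusted over the list alone. These families have many processed pseudogenes, and how shared reads were assigned is not given in the sources used here. The median was 0.70, and 0.27 after correction, with an adjusted camera p of 3.8e-05 and an adjusted p of 0.460 with an estimated correlation. Ribosome biogenesis genes did not pass as a list (27 tested; adjusted p = 0.432). Their median was 0.02 while their mean was -0.11 and the test pointed downward, and the median was -0.27 after correction. UTP20 was 6.05-fold lower (3.46-fold after correction, and 4.14-fold to 11.6-fold with 1 library left out), and adjusted over the list alone 3 were lower. The list passed without Rib_CA 1 (median -0.42; adjusted p = 0.0184). COX5B, NDUFA1, RPLP1 and RPS19 lost their calls on leaving out either DMSO library.

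Lysosome and autophagy genes were higher as a list, with none of 27 passing singly and 4 higher adjusted over the list alone. PSAP, the precursor of the saposins, had a log2 fold change of 1.25 ± 0.30 (adjusted p = 0.0550). The median was 0.52, and 0.36 after correction, with an adjusted camera p of 0.000990 and an adjusted p of 0.403 with an estimated correlation. Targets of the oxidative stress factor NRF2 were higher, with OSGIN1 (2.80-fold) the 1 of 23 that rose, also 1 adjusted over the list alone. The median was 0.36, and 0.39 after correction, with an adjusted camera p of 0.0136 and an adjusted p of 0.418 with an estimated correlation, and the call was lost without Rib_CA 2 (median 0.164; adjusted p = 0.276). Cholesterol synthesis genes were higher, with PMVK (2.87-fold, and 1.77-fold after correction), a kinase of the mevalonate pathway, the 1 of 24 that rose, and 2 adjusted over the list alone. The median was 0.37, and 0.31 after correction, with an adjusted camera p of 0.0272 and an adjusted p of 0.488 with an estimated correlation. That call was lost without DMSO 1 (median 0.254; adjusted p = 0.196) and without Rib_CA 1 (median 0.278; adjusted p = 0.259). Glycolysis and hypoxia genes did not pass as a list (19 tested; adjusted p = 0.0739; median 0.30, and -0.03 after correction). VEGFA, the endothelial growth factor gene, rose from 44.1 ± 0.31 to 179 ± 57.3 CPM (4.06-fold; adjusted p = 0.0285), the 1 member that passed, also 1 adjusted over the list alone. That list passed without Rib_CA 1 (adjusted p = 0.00878) and with total-count scaling (median 0.498; adjusted p = 0.0407). OSGIN1, PMVK and VEGFA lost their calls on leaving out either DMSO library.

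Mesenchymal and invasion genes did not pass as a list (24 tested; adjusted p = 0.727; median 0.17, and 0.01 after correction). ZEB1, a repressor of epithelial genes, was 3.25-fold lower (1.99-fold after correction), the 1 that fell, also 1 adjusted over the list alone. Luminal breast epithelial markers did not pass as a list (13 tested; adjusted p = 0.385; median 0.24, and -0.15 after correction). The tight junction gene CLDN4 rose 2.98-fold, the 1 that rose, with 2 adjusted over the list alone. ZEB1 and CLDN4 lost their calls on leaving out either DMSO library. Of the fibroblast markers 2 passed the filter on low counts, with a median of -0.78, and of the leukocyte markers 4, with a median of 0.11. These lists were too small for the list test, and none of their members was called over all genes or adjusted over the list alone. COL1A1 lay at 7.79 ± 0.37 CPM in DMSO and 4.90 ± 1.15 CPM in Rib_CA, and CD74 at 16.9 ± 7.10 and 14.97 ± 11.4 CPM (log2 fold change -0.18, and -0.83 after correction; -1.349 to 0.443 with 1 library left out).

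Genes called higher and lower differed in base composition and length. The median GC content of the longest transcript was 57.3% for the 275 genes called higher, 40.3% for those called lower and 49.1% for the rest. Median transcript lengths were 2.20, 6.05 and 3.59 kb, and median genomic spans 12.6, 91.8 and 31.5 kb, in the same order. Across 13608 genes with values, which are not independent replicates, the log2 fold change had a Spearman rho of 0.48 with GC content, -0.35 with transcript length and -0.40 with genomic span. The log2 ratio of DMSO 2 to DMSO 1 had a rho of 0.31 with GC content, and that of Rib_CA 2 to Rib_CA 1 one of -0.42. After the GC and length correction, all 974 called genes kept their sign and 645 stayed at least 2-fold different, while their median absolute log2 fold change went from 1.73 to 1.17 and their median SE from 0.31 to 0.28.

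**Figure D3:**
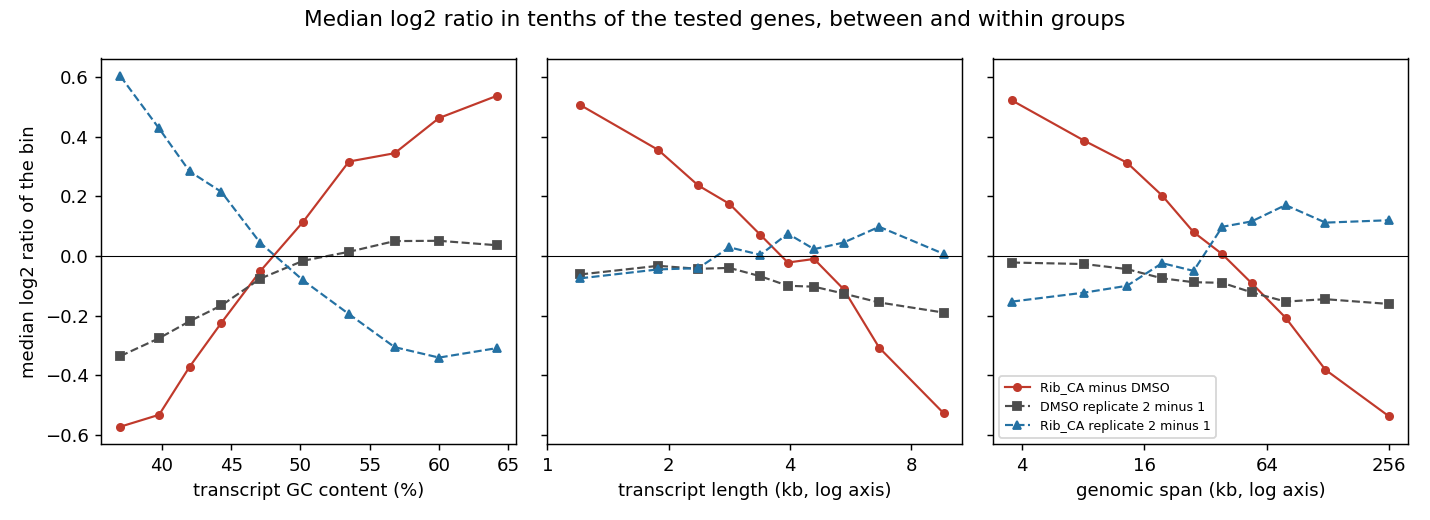
Median log2 ratio of the tested genes, in 10 equal bins ordered by transcript GC content (left), transcript length (middle, log axis) and genomic span (right, log axis), for Rib_CA over DMSO (red) and for replicate 2 over replicate 1 within DMSO (grey) and within Rib_CA (blue). Between groups the median went from -0.57 in the lowest to 0.54 in the highest bin of GC content, and within Rib_CA from 0.60 to -0.31.

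Several of the main genes are placed here on GRCh38 with GENCODE release 29 gene limits. CDKN1A (ENSG00000124762) spans chromosome 6 from 36676460 to 36687339. PMAIP1 (ENSG00000141682) spans chromosome 18 from 59899948 to 59904306. TRIB3 (ENSG00000101255) spans chromosome 20 from 362835 to 397559. CXCL8 (ENSG00000169429) spans chromosome 4 from 73740506 to 73743716, on the same chromosome as CXCL1, from 73869393 to 73871242, CXCL3, from 74036589 to 74038807, and CXCL2, from 74097035 to 74099293. MKI67 (ENSG00000148773) spans chromosome 10 from 128096659 to 128126385, and BCL2L2 (ENSG00000129473) chromosome 14 from 23298790 to 23311759. All of these are protein-coding genes, and the values given for each are counts over the whole gene.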

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

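The GC correction, the GC and length correction, the crossed pairing and the run without mitochondrially encoded genes were chosen only after the results were seen. Where tested, none of the 974 called genes changed sign under any alternative tried. Counts of genes higher and lower were 298 and 753 with DESeq2's size factors, 276 and 692 after thinning, 224 and 658 with limma-voom, and 383 and 749 without mitochondrially encoded genes, against 275 and 699. They were 448 and 876 without a filter, 418 and 808 (415 and 805 at least 2-fold) with the stricter filter, 260 and 328 with total counts alone, and 991 and 1464 (810 and 1311 at least 2-fold) with DESeq2. Beyond the numbers of genes tested, 16177 and 10940 against 13667 for the filters, the cause was not tested. Both corrections gave 0 and 0, with smallest adjusted p of 0.0642 and 0.0798. The called genes' median absolute log2 fold change shrank from 1.73 to 1.26 and 1.17 and their median SE from 0.31 to 0.29 and 0.28, and 715 and 490 of them had an adjusted p under 0.1, while prior degrees of freedom went from 4.69 to 4.06 and 3.96. Fold changes were smaller for 917 and 929 of the 974 and p larger for 887 and 905. Of the 974, 413 and 336 kept a p within the largest called before (0.003563), so these lost their calls to the adjustment, as 635 and 549 genes had so small a p against 974 before. With the main test's degrees of freedom kept, a check chosen after the result was seen, the corrected fits would call 360 and 0 genes. Without 1 library the counts ranged from 36 (without DMSO 1) to 1234 (without Rib_CA 1) higher and from 137 to 1634 lower, or from 36 to 997 and from 137 to 1537 at least 2-fold. Calls fell when a DMSO library was left out and rose when a Rib_CA library was, and 129 genes, 21 higher and 108 lower, were called in all 4 of these fits. Of the 60 named genes that passed, 26 did so in all 4, while 33 lost the call without DMSO 1, 26 without DMSO 2 and 1, CXCL3, without Rib_CA 1. With the replicate number as a block the counts were 260 and 687, of which 207 and 618 were shared with the fit without it, and no list call changed. The deviations of same-numbered libraries correlated at -0.19 over all genes and -0.38 over genes with a mean log2 CPM above 5, with only 2 pairs, so the numbers are not taken to pair the libraries. A crossed pairing gave 724 and 1267 genes, 652 and 1183 of them at least 2-fold. The 10 lists called higher and 5 called lower became 0 and 0 with an estimated correlation and 0 and 0 with fry, whose smallest adjusted p was 0.0509, for the ATF4 list. Without 1 library 8 to 11 lists were higher and 5 to 6 lower. Directions turned only in lists and genes that were not called. With 1 library left out, the direction of the test turned for the cyclin D module (medians 0.03 to 0.151; turned without DMSO 2), the mesenchymal list (-0.195 to 0.44; without DMSO 1 and without Rib_CA 1) and ribosome biogenesis (-0.419 to 0.406; without Rib_CA 2). The log2 fold change then ranged from -1.349 to 0.443 for CD74, -0.391 to 1.636 for H2BC4, -0.081 to 0.947 for MDM2 and -0.108 to 0.271 for CCND1. CD74 became 0.003 with total counts alone. CCND1 became -0.021 with the GC correction, and CD14 -0.152 and BAX -0.094 with the GC and length correction. The cause of these turns was not tested.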

Other observations

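The genes of the first paragraph were singled out after their values were seen. Every test of an explanation below was chosen after the result was seen, except the one that sets aside p53 targets shared with the ATF4 response. The uncorrected tests of genes and lists quoted with them, and the fits with a library left out, were planned. Of the 129 genes called with any library left out, 104 were in none of the fixed lists. Among the 10 of these that were higher, G0S2, an inhibitor of the lipase ATGL, rose from 80.4 ± 13.2 to 450.3 ± 7.62 CPM (SD, n = 2; 5.60-fold). ADM2, a peptide hormone gene, rose 9.01-fold, the complement gene CFB 7.66-fold and IRAK2, a kinase of interleukin 1 receptor signalling, 5.90-fold. Larger rises were in ENSG00000196826, ENSG00000167807, BIVM-ERCC5 (33.8-fold) and PTGES3L-AARSD1 (14.6-fold), each with a mean under 10 CPM in Rib_CA, and in C15orf48 (10.4-fold). Among the 94 that were lower, HIF1A, the oxygen-sensing transcription factor gene, fell from 678 ± 22.3 to 145 ± 79.1 CPM (4.67-fold). The cohesin gene SMC3 was 6.42-fold lower, the cohesin regulators PDS5B 6.55-fold and NIPBL 6.17-fold, and the condensin gene SMC2 5.23-fold. TET2, which oxidises methylcytosine, was 6.84-fold lower, ARID2, of a SWI/SNF complex, 5.81-fold, and the scaffold gene IQGAP1 5.21-fold. The largest falls of the set were in CREB3L3 and ENSG00000069712, at means of 0.938 and 5.88 CPM in DMSO and both at 0 CPM in Rib_CA. After the GC and length correction the log2 fold changes were 1.87 ± 0.26 (SE) for G0S2, -1.51 ± 0.57 for HIF1A and -2.02 ± 0.44 for SMC3, against 2.485, -2.223 and -2.682 before. They went from -2.711 to -1.845 for PDS5B, from -2.626 to -1.588 for NIPBL, from -2.387 to -1.601 for SMC2, from -2.773 to -1.984 for TET2, from -2.539 to -1.701 for ARID2 and from -2.382 to -1.796 for IQGAP1. With 1 library left out, the fold change ranged from 3.90 to 7.77 for IRAK2 and, among the lower, from 3.38 to 7.83 for HIF1A.

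Genes called lower were long and poor in GC, and genes called higher short and rich in GC. GC bias that differs between libraries may account for part of this, since libraries of the same group also differed along GC content, with a Spearman rho of 0.31 in DMSO and -0.42 in Rib_CA against 0.48 between groups. At fixed transcript length and genomic span, the standardized coefficient of GC content was 0.327 between groups. It was 0.216 within DMSO and -0.35 within Rib_CA, the latter larger in size than that between groups. A lower output of genes that span a long stretch of genome, as when transcription elongation is impaired, is a second hypothesis. At fixed GC content and transcript length the standardized coefficient of genomic span was -0.147 ± 0.009 (SE over genes) between groups, and 0.019 and -0.013 within them. With 2 libraries per group this coefficient cannot be told apart from other differences between the groups' libraries, and its SE treats genes as independent. Loss of long transcripts through RNA integrity stays open, because the coefficient of transcript length, -0.153 between groups against -0.021 and -0.041 within them, is confounded with treatment and no measure of RNA integrity was used. These explanations do not exclude one another, and the share of each was not estimated.

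The mitosis list was lower with a median of -1.43. The GC and length trend of the libraries as its whole cause is argued against by the corrected median of -1.157, with an adjusted camera p of 6.4e-28 at the preset correlation. 22 of 42 members passed before the correction, while no gene passed after it. A lower share of dividing cells after 24 h of Rib_CA is a possible explanation, which was not tested, and members such as CCNB1 (-0.245, and -0.098 after correction), MAD2L1 (0.069 and 0.638) and CENPA (0.639 and 0.341) did not go with the list, while CDC20 (-0.014 and -0.623) and AURKB (-0.186 and -0.799) lay nearer to it after correction. With the correlation estimated (0.157), the list's adjusted p was 0.403 before correction, so the list passed camera only at the preset correlation. The estimated setting also rests on 2 residual degrees of freedom. It therefore cannot tell whether the list's separation from other genes depends on the correlation.

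The p53 target list was higher (adjusted p = 0.00209 at the preset correlation, and adjusted p = 0.403 with an estimated correlation), while MDM2 and BAX did not pass, with log2 fold changes of 0.348 ± 0.390 and 0.575 ± 0.270 (SE), and of 1.27 ± 0.434 and -0.094 ± 0.211 after the GC and length correction. The GC and length trend as its whole cause is argued against by the corrected median of 0.552 against 0.613 before, with an adjusted camera p of 0.000975 at the preset correlation. A candidate explanation is that the list rose through members that ATF4 and CHOP also induce, 8 of them written down before the test, SESN2, PMAIP1, BBC3, GDF15, TNFRSF10B, GADD45A and CDKN1A among them. These 8 had a median of 1.99, and 5 of them rose, which are all the members that rose. The other 27 had a median of 0.403, with 18 of 27 higher and none called higher, and they did not pass camera at the preset correlation. Camera's part of the prediction written beforehand was met, but the median stayed above the bound set for the shared members to account for the list, so a p53 response and a stress response cannot be told apart in these libraries.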
